A study of Mus musculus with 7 samples.

How the data were processed

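RNA was sequenced in 5 libraries and hMeDIP in 2, each the only library of its group, with groups taken from the sample titles. TruSeq libraries were made from total RNA, and hMeDIP libraries from sonicated genomic DNA ligated to adaptors, denatured and precipitated with an antibody to hydroxymethylcytosine, per the labels' protocols. Gene levels were estimated with RSEM 1.1.21 on the mm9 mouse genome, per the submitters' processing notes. The deposited gene files give the authors' expected counts, estimated numbers of reads per gene that are not scaled to library size. A further deposited column gives the fraction of transcripts that each gene takes, which sums to 1 in each library and times 1000000 is TPM. Between 20.6% and 22.3% of expected counts were not whole (tolerance 0.005), since RSEM shares reads that match several transcripts. The read aligner for RNA and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The hMeDIP reads were aligned with Bowtie2 2.1.0 and peaks called with MACS 1.4.2 on mm9, per the submitters' processing notes, with 1 deposited peak list per library. The score in the deposited peak lists is taken to be the caller's p-value on a scaled negative log10 axis, with a lowest value of 50. The control, the number of tags and the caller's settings are not given in the sources used here.

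Expected counts were rounded to whole numbers first. Library sizes were scaled with TMM factors from all 5 RNA libraries (edgeR 4.0.16 in R 4.3.3), which were 1.0296 for DR, 0.9376 for Tet1CD, 1.0214 for Tet1CDmut, 1.0015 for Tet2CD and 1.0127 for Tet2CDmut. Log2 ratios used a prior count of 2 scaled to library size. With 1 library per group there is no test, no p-value and no standard deviation between replicates, and a ratio compares libraries, not conditions. A gene was called higher or lower by a fixed rule of size, with a log2 ratio of at least 1, at least 50 counts in the higher library, and a 95% interval of the ratio that excludes 1. The interval is the exact conditional binomial (Clopper-Pearson) interval of the 2 counts. It covers counting error only, since reads without molecular identifiers are not independent molecules and a single culture carries no replicate spread. Genes with at least 50 counts in either library counted as measured. A gene that reached 50 counts in 1 library alone counted as measured because it was high there, which favours increases in that library. A count of 0 was taken to allow up to 3 counts in a library. Where the lower count was 0, the lower limit of the interval of the ratio is given in place of a fold. A group of 29 gene lists was summarised by the median log2 ratio of members with at least 50 counts in 1 of the 5 libraries. Each median was given its percentile among 10000 random lists of equal size matched on mean expression in 20 bins, and was described where it lay below percentile 2.5 or above 97.5. Lists with fewer than 3 measured members were given by gene. Overlaps of calls that share a library were set beside independent lists and 20 simulations of counting error alone, with 1 profile for all libraries.

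Peaks were compared with bedtools 2.31.1 by an overlap of at least 1 bp, beside 100 shuffles within chromosomes. Shares of peaks carry Wilson 95% intervals. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

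The rule of size, the gene lists, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. Named were Tet1, Tet2, Tet3, Pou5f1, Sox2, Klf4 and Myc. For Tet1CD and Tet2CD against both references, and for Tet1CD against Tet2CD, up to 12 genes per direction were named with the interval bound nearest to 1 that lay farthest from 1, among genes with at least 100 counts in the higher library and a gene name. For the other comparisons up to 5 genes per direction were named by the same ranking, and for each described list up to 4 members with the largest change. Other genes named in the text were chosen after their values were seen: in the report Chrna1, Hbb-y, Hist1h1c, Hist1h2bc and Lpl, changed members of sparsely measured lists, with Emr1, Csf1r, Lyz1, Tyrobp, Ptprc and Nanog. Near-identical copies that share reads (Amd1 and Amd2, Tgtp1 and Tgtp2) are treated as uncertain and given as sums. Some genes that the rule names are not reported here.

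The procedure was tested on simulated data. In a simulation of Tet1CD over DR on 7760 genes, 100% of genes changed 3-fold, 97.6% of those changed 4-fold and 100% of those changed 8-fold were called, as were 2.56% of those changed 1.5-fold and 3 of 7696 unchanged genes. For Tet2CD over DR on 7704 genes, 96.1%, 97.9% and 100% were called, 0 of the 46 genes changed 1.5-fold, and 1 of 7940 unchanged genes. The interval covered the simulated ratio for 95.3% of genes in both, and 5.0% of 200 random lists were described in Tet1CD over DR. The simulated counts held counting error only, and the random lists were compared, without matching on expression, with lists drawn the same way. These values therefore follow largely from the design and do not cover lists of genes that move together between cultures. Totals of 2153050 to 2612927 counts make 1 count worth about 0.0000464% of the DR library, so genes under 50 counts are known only to within wide intervals.

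Alternatives were DESeq2 1.42.0 size factors, total counts, a minimum of 10 or 200 counts, a prior count of 0.5, log2(TPM + 1), random lists without matching, list means, a peak score of at least 100, reciprocal overlap and peak lists of equal length. Removal of a trend with gene length and a restriction to genes with whole expected counts were added after seeing the data, as were list medians without members that reached 50 counts in the first library of a comparison alone. A deposited table of the whole series was checked but used in no comparison, because its column names do not match the values of the single libraries. The gene table at hand follows another assembly than mm9, so peaks were not assigned to genes.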

Results

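Gene expression and hydroxymethylated DNA were measured in mouse embryonic fibroblasts carrying the OG2 transgene, a reporter in which Pou5f1 regulatory sequence drives GFP, during reprogramming toward pluripotency. The cells were at passage P2 and of mixed 129SVJ, C57B6 and CBA background. Each culture overexpressed the construct it is named for, Tet1CD, Tet1CDmut, Tet2CD, Tet2CDmut or DR, during this reprogramming. Tet enzymes oxidise 5-methylcytosine to 5-hydroxymethylcytosine. The labels do not spell out "CD", "mut" or "DR", nor do they name the reprogramming factors used. RNA was sequenced 3 days after infection in 5 libraries, 1 per construct. Enrichment of hydroxymethylated fragments with an antibody followed by sequencing (hMeDIP-seq) was performed 1 day after infection in 2 libraries, Tet1CD and Tet2CD. The RNA libraries held 2153050 (DR), 2153774 (Tet1CD), 2612927 (Tet1CDmut), 2392482 (Tet2CD) and 2274746 (Tet2CDmut) expected counts over 20325 genes. At this depth 7306 to 8335 genes per library reached 50 counts, and a count of 0 allowed a share of up to 0.000115% to 0.000139% of a library. Each group had 1 library, so no difference could be set against replicate spread. All intervals are 95% intervals that cover counting error only, and the words rose and fell denote genes that differed at least 2-fold between 2 libraries with at least 50 counts in the higher one.

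The construct labels were first set against the levels of the Tet genes. Tet1 stood at 2436 CPM (counts scaled to a library of 1000000) in Tet1CD and 4110.3 in Tet1CDmut, against 79.4 in DR, 5.01 in Tet2CD and 11.7 in Tet2CDmut. Tet2 stood at 2559.2 CPM in Tet2CD and 3966.3 in Tet2CDmut, against 275.6 in DR. Over DR, Tet1 was 30.7-fold higher in Tet1CD (interval 26.4 to 35.9) and 51.8-fold higher in Tet1CDmut (44.6 to 60.4). Tet2 was 9.28-fold higher in Tet2CD (8.54 to 10.1) and 14.4-fold higher in Tet2CDmut (13.3 to 15.6). Both unmutated constructs were present at a lower level than their mutated forms, by 1.69-fold for Tet1 (1.63 to 1.75) and 1.55-fold for Tet2 (1.5 to 1.6). In the Tet1CD library Tet2 fell to 82 counts from 611 in DR, 6.79-fold lower (5.38 to 8.66), whereas Tet1CDmut held 535. Tet3 counts were 94 in Tet1CD and 202 in DR, 1.96-fold lower (1.53 to 2.53). Tet1 itself was 15.9-fold lower in Tet2CD than in DR (8.85 to 31.3) and 6.77-fold lower in Tet2CDmut (4.5 to 10.6). A part of the 176 Tet1 counts in DR may be reads of the Tet1CD library, as given under other observations. The folds of Tet1 against DR are therefore uncertain beyond their intervals.

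Transcripts of the usual reprogramming factors were abundant in every library except for Myc. Pou5f1 held 7014 counts in DR, 8976 in Tet1CDmut, 8098 in Tet2CD and 7855 in Tet2CDmut, and 3281 in Tet1CD. Its level in Tet1CD was 1.95-fold lower than in DR (1.87 to 2.03), 2.07-fold lower than in Tet1CDmut (1.99 to 2.16) and 2.08-fold lower than in Tet2CD (2.0 to 2.17). Klf4 was 1.47-fold lower in Tet1CD than in DR (1.39 to 1.55) and Sox2 1.28-fold lower (1.2 to 1.37). Myc ranged from 72 to 113 counts, and its ratio of Tet1CD to DR, 1.17, had an interval of 0.84 to 1.64. Reads of an introduced coding sequence and of the endogenous gene were not separated in these counts.

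**Figure D1:**
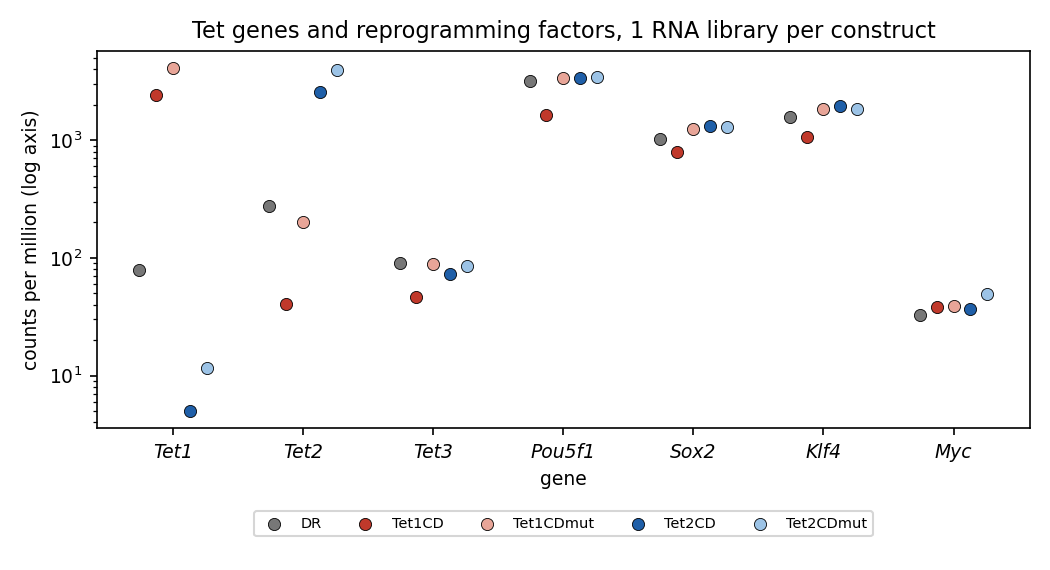
Levels of the Tet genes and reprogramming factors in the 5 RNA libraries, in CPM on a log axis, with 1 point per library coloured by construct. Tet1 stands at 2436 in Tet1CD and 4110.3 in Tet1CDmut, Tet2 at 2559.2 in Tet2CD and 3966.3 in Tet2CDmut, and Pou5f1 in Tet1CD, at 1624.9, lies below the 3164.1 to 3409.8 of the other libraries.

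Whether Tet1CD changed mRNA levels was asked against DR and against the mutated form. Several transcripts at low or moderate counts in the references were far more abundant in Tet1CD. Bckdhb, which encodes a subunit of the branched-chain keto acid dehydrogenase, rose from 153 counts in DR to 7738, 55.5-fold (47.3 to 65.6), and was 93.0-fold above Tet1CDmut (77.0 to 113.3). The germ cell genes Dazl and Tex19.1 held 216 and 158 counts in Tet1CD, 2 and 1 in DR, and 0 each in Tet1CDmut, with lower interval limits of 76.7-fold and 55.9-fold over Tet1CDmut. Psg23, of the pregnancy-specific glycoprotein family, rose from 20 to 1251 counts, 68.7-fold over DR (44.3 to 112.8). Iigp1 and Igtp, which encode interferon-inducible GTPases, fell.

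Of the other genes with the strongest increases over both references, Gpr179 rose 56.9-fold over DR (38.9 to 86.6), Zfp575 45.4-fold (32.3 to 65.8), Glipr1 35.5-fold (18.4 to 78.4), Baiap2l1 25.4-fold (17.6 to 37.9) and Bfsp1 19.7-fold (11 to 38.7). Ttc18 rose from 2 to 478 counts (262.4-fold, 72.2 to 2172.7) and Slc47a1 from 2 to 161 (88.4-fold, 24.1 to 736.0). Dnahc11, an axonemal dynein heavy chain gene, was at 0 in DR and 106 in Tet1CD, with a lower interval limit of 31.0-fold. For 11 genes at 200 or more counts in Tet1CD and 16-fold or more above both mutated forms, Bckdhb, Psg23 and Dazl among them, DR held 483 counts, where the level of the mutated forms would give 242.1. Among the decreases, Iigp1 fell 22.4-fold (13.2 to 41.5) and Igtp 12.2-fold (9.74 to 15.6). The guanylate-binding protein genes Gbp1, Gbp2 and Gbp4 fell 11.1-fold, 11.6-fold and 12.3-fold, and Mpa2l fell 40.1-fold. The summed count of Tgtp1 and Tgtp2, near-identical copies that may share reads, was 85 in Tet1CD and 2400 in DR, 25.7-fold lower (20.7 to 32.3). Msc, which encodes the transcription factor musculin, fell 34.9-fold (18.2 to 77.0). The hormone precursor gene Trh fell 13.8-fold (11.7 to 16.3) and Foxo4 10.3-fold (7.84 to 13.8). The tryptophan tRNA synthetase gene Wars fell from 4374 to 426 counts, 9.35-fold (8.47 to 10.4).

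Proliferation genes formed the largest coordinated decrease by count. Of 42 measured cell cycle genes 30 fell in Tet1CD against DR and 0 rose, with a median log2 ratio of -1.40 at percentile 0 of 10000 expression-matched random lists. Kif11, a spindle motor, fell 5.28-fold (3.89 to 7.3), Bub1b 4.93-fold (3.59 to 6.91), the proliferation marker Mki67 4.63-fold (4.08 to 5.27) and the centromeric histone gene Cenpa 4.49-fold (3.24 to 6.36). Of 49 interferon response genes 22 fell and 1, Dhx58, rose (median -1.08, percentile 0), and Psmb9, an immunoproteasome subunit, fell 9.27-fold from 112 counts to 11. Of 20 DNA methylation genes 6 fell and 1 rose (median -0.57, percentile 0.02, and -0.89 with a minimum of 200 counts). These included Uhrf1, a cofactor of maintenance methylation, at 3.57-fold lower (2.94 to 4.35), Parp1 at 2.58-fold (2.21 to 3.02), the maintenance methyltransferase Dnmt1 at 2.4-fold (2.09 to 2.75) and Dnmt3a at 2.23-fold (1.8 to 2.78). Of 36 listed pluripotency genes 5 were measured and 4 fell (median -1.53, percentile 0.03), among them Cdh1 5.47-fold (3.3 to 9.57), Mybl2 2.95-fold (2.19 to 4.04) and L1td1 2.84-fold (2.25 to 3.61). The other 30 pluripotency genes in the files stayed under 50 counts in all 5 libraries, Nanog at 1 count or less. Against Tet1CDmut these medians were -1.35 for the cell cycle (30 of 42 fell), -1.25 for interferon (25 of 49 fell and 1 rose), -0.59 for DNA methylation (5 of 20 fell) and -1.54 for pluripotency (4 of 5 fell).

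Matrix and stress genes moved the other way. Of 35 mesenchymal and matrix genes 13 rose and 0 fell in Tet1CD against DR (median log2 ratio 0.76, percentile 100.0), with Thbs1 at 6.86-fold (6.14 to 7.69), Tagln at 4.33-fold (2.55 to 7.72), the collagen gene Col1a1 at 3.37-fold (3.16 to 3.59) and Sparc at 3.16-fold (3.02 to 3.3). Of 26 p53 and senescence genes 13 rose and 2 fell (median 0.94, percentile 100.0). The stress cytokine gene Gdf15 rose 16.3-fold (8.02 to 38.7), Plk2 3.99-fold (3.49 to 4.58), Dcxr 3.53-fold (2.48 to 5.12) and the proapoptotic gene Pmaip1 3.37-fold (2.16 to 5.42). Inflammatory genes rose in 7 of 14 cases with 0 falling (median 0.99, percentile 100.0), led by Ptgs2, the inducible cyclooxygenase gene, at 6.07-fold (5.1 to 7.28) and the chemokine gene Ccl2 at 3.94-fold (3.39 to 4.61). In the TGF-beta response list 3 of 16 rose (median 0.48, percentile 99.78, and 0.29 with TPM), with Ctgf at 3.11-fold (2.44 to 4.0). In the unfolded protein and amino acid stress list 3 of 22 rose (median 0.44, percentile 99.92, and 0.25 with TPM), with Ddit3 at 3.6-fold (2.09 to 6.48). Against Tet1CDmut the medians were 0.71 for the matrix (11 of 35 rose), 0.90 for p53 (12 of 26 rose), 0.80 for inflammation (6 of 14 rose), 0.31 for TGF-beta (4 of 16 rose) and 0.44 for unfolded protein stress (3 of 22 rose). With TPM the last 2 were 0.14 and 0.27. Tagln, Gdf15, Pmaip1 and Ddit3 reached 50 counts in Tet1CD alone, so that being measured was not independent of being higher there. Without such members 11 of 33 matrix, 11 of 24 p53, 4 of 11 inflammatory, 2 of 15 TGF-beta and 1 of 20 unfolded protein stress genes rose over DR, with medians of 0.73, 0.86, 0.91, 0.48 and 0.38.

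Markers of other cell types were examined as well. Of 20 macrophage and leukocyte markers 5 were measured, and all 5 rose in Tet1CD over DR (median log2 ratio 3.25, percentile 100.0), with Itgam, an integrin subunit, at 23.4-fold (13.2 to 45.9), Itgb2 at 13.3-fold (6.98 to 28.4), Cd68 at 319 counts against 35 (interval of the ratio 7.04 to 14.6) and Laptm5 at 7.49-fold (5.81 to 9.79). Itgb2 was 1 of 2 measured markers that reached 50 counts in Tet1CD alone, and without these 3 of 3 rose with a median of 3.25. The other 15 markers had 18 counts or fewer each in Tet1CD and summed to 112 against 26 in DR, a 4.73-fold difference (3.06 to 7.55). Among them Emr1 held 18 counts against 3 in DR, Csf1r 15 against 1, Lyz1 13 against 0 and Tyrobp 4 against 0, while Ptprc held 3 against 6. The leukocyte median over Tet1CDmut was 2.97, where all 5 rose. Neural and glial genes went both ways, with 4 of 9 rising and 3 falling (median 0.81, percentile 99.97, but 93.6 with list means), as Nefm rose 9.1-fold (7.04 to 11.9) and Nefl 2.91-fold (2.7 to 3.15) while Stmn2 fell 2.81-fold (2.44 to 3.24). Over Tet1CDmut 3 neural genes rose and 3 fell (median 0.57, percentile 99.5, but 88.3 with list means). The TET enzyme list went both ways, since Tet1 rose with its construct and Tet2 fell, so that its median of -0.95 (percentile 1.14, but 86.55 with list means) is the value of Tet3 alone. The 4 reprogramming factors lay at -0.46 over DR (percentile 4.7) and -0.70 over Tet1CDmut (percentile 1.21, but 5.5 with list means and 3.1 without matching on expression), where 1 (Pou5f1) fell.

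Several lists did not stand apart from random lists in Tet1CD over DR. These were the epithelial list (median log2 ratio 0.19, percentile 85.43, 2 of 13 rose and 3 fell), BMP response (0.57, percentile 90.38, 2 of 5 rose), imprinted genes (0.21, percentile 94.49, 4 of 21 rose and 2 fell), glycolysis and hypoxia (0.29, percentile 97.25, 4 of 23 rose), cholesterol synthesis (-0.04, percentile 28.12, 0 of 23 changed), heat shock (0.27, percentile 91.88, 0 of 11 changed), Hox genes (-0.17, percentile 27.27, 0 of 8 changed) and endothelial markers (0.62, percentile 95.54, 1 of 3 rose). Lists with fewer than 3 measured members are given by gene. Of 58 germline genes Dazl and Tex19.1 were the 2 measured. Both reached 50 counts in Tet1CD alone, so that being measured was not independent of being higher there. Of the replication-dependent histone genes, whose transcripts are usually lost in poly(A) selection and can mark differences in RNA selection, Hist1h1c and Hist1h2bc rose 2.8-fold (2.04 to 3.89) and 4.39-fold (3.29 to 5.94), while the other 21 held 10 counts or fewer each and summed to 35 in Tet1CD and 30 in DR. Across all measured genes the median log2 ratio was 0.11 for the shortest 10% and -0.15 for the longest 10% by length. The adipocyte gene Lpl rose 2.25-fold (1.98 to 2.56) and the muscle gene Chrna1 3.51-fold (2.73 to 4.55), while the embryonic globin gene Hbb-y fell 3.01-fold (2.51 to 3.63). Neither of the 2 measured cartilage and bone markers changed, 0 of 36 early lineage regulators reached 50 counts, and mitochondrially encoded genes were not analysed here because 0 of 13 carried a listed name in the files.

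In numbers, 662 of 8215 measured genes rose and 619 fell in Tet1CD against DR (15.6%), and 608 rose and 661 fell of 8650 against Tet1CDmut (14.7%). Both ratios passed in the same direction for 538 higher and 517 lower genes. Independent lists would share 49.3 and 50.1 such genes, and 20 simulations of counting error alone gave at most 1. The comparisons share the Tet1CD library, so any deviation of that single library enters both ratios, which neither figure covers. The balance of higher and lower genes depended on the scaling of the libraries. Of the genes called against DR 51.7% were higher with TMM factors, 41.2% with total counts and 37.7% with TPM, and against Tet1CDmut 47.9%, 38.5% and 35.5%. The median log2 ratio of all genes moved from -0.005 to -0.138 with total counts and -0.189 with TPM against DR, and from -0.019 to -0.141 and -0.185 against Tet1CDmut.

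**Figure D2:**
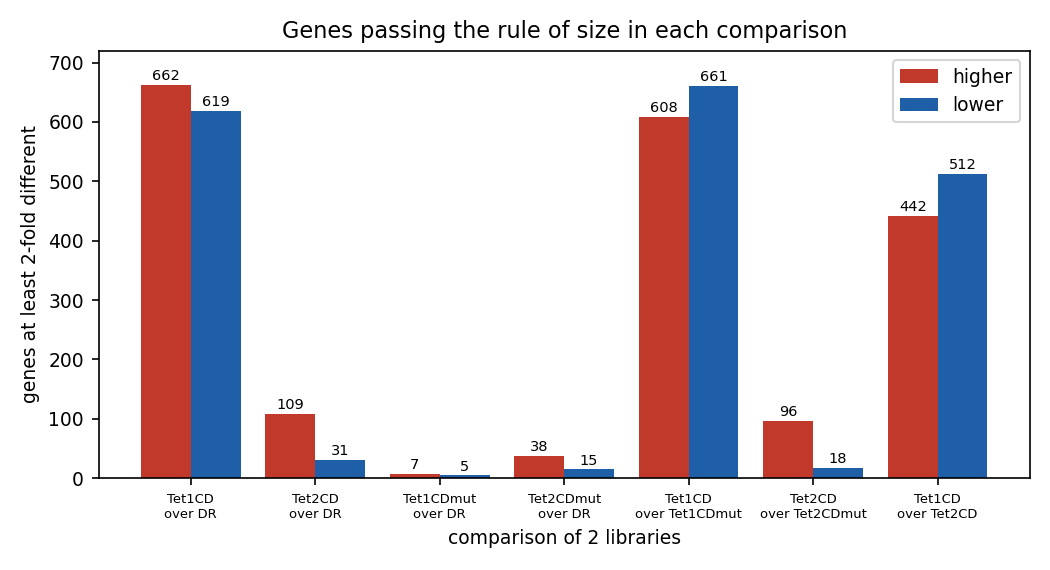
Number of genes at least 2-fold higher (red bars) or lower (blue bars) in each of the 7 comparisons of 2 RNA libraries. The comparisons of Tet1CD with DR, Tet1CDmut and Tet2CD hold 662 and 619, 608 and 661, and 442 and 512 genes, while Tet1CDmut over DR holds 7 and 5.

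The same questions were put to Tet2CD, against DR and against Tet2CDmut. Fewer genes differed, and interferon response genes were the group with the most increases. Oas3, a sensor of double-stranded RNA, rose from 69 counts in DR to 279, 3.74-fold (2.86 to 4.94), and was 5.71-fold above Tet2CDmut (4.18 to 7.95). Ifit3 rose 3.61-fold over DR (2.84 to 4.64) and 2.98-fold over Tet2CDmut (2.39 to 3.74), and the ubiquitin-like modifier gene Isg15 rose 2.83-fold (2.34 to 3.44) and 2.86-fold (2.37 to 3.47). Glipr1, Gpr179 and Baiap2l1, which also rose in Tet1CD, were 12.2-fold (6.23 to 27.4), 7.95-fold (5.32 to 12.3) and 7.31-fold (4.99 to 11.1) higher in Tet2CD than in DR. The mitochondrial leucine tRNA synthetase gene Lars2 fell from 3613 to 1495 counts, 2.61-fold (2.46 to 2.78). Its counts also varied among the other libraries, with 1195 in Tet1CD, 2003 in Tet1CDmut and 3059 in Tet2CDmut, so its fall was not particular to Tet2CD.

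Among other genes higher than in both references were Apol9b at 3.3-fold over DR (2.68 to 4.09), Mst1 at 7.67-fold (4.39 to 14.5), Dhx58 at 4.54-fold (2.82 to 7.64), Srgn at 3.7-fold (2.69 to 5.17), Ifi44 at 3.27-fold (2.42 to 4.48) and the purinergic receptor gene P2rx7 at 3.92-fold (2.52 to 6.33). Gpr50 fell 3.08-fold (2.18 to 4.41) and Necab1 2.31-fold (1.78 to 3.0) against DR. Against Tet2CDmut, Acpp fell 3.34-fold (2.71 to 4.16), Prune2 2.65-fold (2.17 to 3.26) and Prom1 2.75-fold (1.94 to 3.97). Acpp and Prune2 held 116 and 136 counts in Tet2CD and 77 and 132 in DR. Their ratios thus come from high values in Tet2CDmut, 373 and 347. Of 49 interferon response genes 14 rose over DR and 0 fell (median log2 ratio 0.69, percentile 100.0), and 8 rose over Tet2CDmut (median 0.38). Without the 2 members that reached 50 counts in Tet2CD alone, 12 of 47 rose over DR (median 0.68). The members that rose most in Tet2CD did not all fall in Tet1CD. Dhx58 and Oas3 held 80 and 110 counts in Tet1CD against 21 and 69 in DR, while Ifit3 and Mx2 held 42 and 9 against 85 and 13. Iigp1, Igtp and Gbp2, which fell in Tet1CD, held 554, 1584 and 2612 counts in Tet2CD against 345, 1062 and 1843 in DR. Of 5 leukocyte markers 3 rose over DR (median 1.28, percentile 99.99, and 0.57 with a minimum of 10 counts), namely Itgam at 7.02-fold (3.83 to 14.1), Cd68 at 2.64-fold (1.78 to 4.0) and Laptm5 at 2.47-fold (1.86 to 3.3), and 2 rose over Tet2CDmut (median 1.2). Cell cycle genes had a median of -0.31 over DR and -0.24 over Tet2CDmut, both at percentile 0, but 0 of 42 passed 2-fold. The p53 list had medians of 0.25 and 0.21 with 0 and 1 of 26 genes rising, the latter Trp53inp1 at 2.11-fold (1.83 to 2.45).

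Smaller shifts of Tet2CD over DR were seen in the inflammatory list (median log2 ratio 0.44, percentile 100.0), where Ccl2 rose 2.3-fold (1.96 to 2.7), and the pluripotency list (-0.46, percentile 0.16), where Tbx3 fell 2.24-fold (1.38 to 3.73). With a minimum of 10 counts the pluripotency median was -0.05. The TET enzyme median of -0.31 (percentile 0.64, but 2.65 without matching on expression) is the value of Tet3 alone, between the higher Tet2 and the lower Tet1. The epithelial median was -0.16 (percentile 1.14, but 40.0 with list means) although its 1 changed member, the keratin gene Krt8, rose 2.06-fold (1.57 to 2.71), and with a minimum of 200 counts the median turned to 0.19. Over Tet2CDmut the endothelial (0.48) and cholesterol (-0.12) lists stood apart with 0 members past 2-fold. The TGF-beta (-0.15, percentile 1.27) and inflammatory (0.16, percentile 97.68) lists did so by their medians only, with 0 members past 2-fold, since list means gave percentiles of 4.25 and 91.15. The inflammatory median was 0.31 with a minimum of 200 counts. Altogether 109 of 8224 genes rose and 31 fell against DR (1.7%), and 96 rose and 18 fell of 8284 against Tet2CDmut (1.38%). Against both, 53 rose and 7 fell, where independent lists would share 1.29 and 0.0686 and simulations of counting error alone shared 0. Both ratios share the Tet2CD library, so a deviation of that library enters both. The copies Amd1 and Amd2 exchanged their counts between libraries, with sums of 276 in DR, 311 in Tet2CD and 309 in Tet2CDmut, so that their apparent change was treated as uncertain.

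The mutated forms were compared with DR. Of the 4 other libraries Tet1CDmut lay closest to DR, with a correlation of 0.9844 across 8818 genes on the log2 scale. The summed count of the copies Tgtp1 and Tgtp2 was 3351 in Tet1CDmut and 2400 in DR, 1.16-fold higher (1.1 to 1.22), so that the larger apparent change of Tgtp2 alone was treated as uncertain. Lars2 fell 2.17-fold (2.06 to 2.29). In Tet2CDmut, Acpp rose from 77 to 373 counts, 4.66-fold (3.64 to 6.04), Prune2 rose 2.53-fold (2.06 to 3.11), and the protein kinase C gene Prkcb fell from 957 to 356, 2.79-fold (2.47 to 3.16). Sdpr and Mtss1l fell 2.12-fold (1.65 to 2.76) and 2.05-fold (1.58 to 2.69). In all 7 genes rose and 5 fell of 8399 in Tet1CDmut (0.143%), and 38 rose and 15 fell of 8108 in Tet2CDmut (0.654%).

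Interferon response genes lay slightly above DR in both mutated forms. The median log2 ratio was 0.22 in Tet1CDmut, where 0 of 49 rose, and 0.28 in Tet2CDmut, where 2 rose, Gbp2 at 2.17-fold (2.05 to 2.29) and Psmb8 at 2.15-fold (1.8 to 2.57). In both cases the median was at percentile 100.0. The reprogramming factors had medians of 0.24 and 0.27 with 0 of 4 past 2-fold. Medians of the inflammatory (0.22) and cholesterol (0.12) lists in Tet2CDmut also stood above random lists with 0 members past 2-fold. In Tet1CDmut the epithelial list (0.16, percentile 99.47) and glycolysis and hypoxia (0.08, percentile 98.5) did so by their medians only, since list means gave 96.45 and 95.1, and glycolysis had 94.55 without matching on expression. The inflammatory median was 0.10 with a minimum of 200 counts.

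The Tet1CD and Tet2CD libraries were then compared directly. Interferon response genes were the list with the most differing genes, with 38 of 49 lower in Tet1CD and 0 higher (median log2 ratio -1.60, percentile 0). Iigp1 was 33.3-fold lower (19.7 to 61.4), Igtp 16.9-fold (13.5 to 21.5), the immunoproteasome gene Psmb8 16.5-fold (10.8 to 26.2), Gbp2 15.2-fold (12.8 to 18.1) and Ifi47 14.4-fold (10.9 to 19.4). Bckdhb was 28.1-fold higher in Tet1CD (25.1 to 31.5), Psg23 33.0-fold (24.5 to 45.5), Psg29 17.7-fold (9.03 to 39.5), Zfp575 24.2-fold (19 to 31.2), Tex19.1 17.0-fold (9.27 to 34.8) and the leukocyte receptor gene Cd84 10.1-fold (7.45 to 13.9). Dazl stood at 216 counts in Tet1CD and 1 in Tet2CD.

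Cell cycle genes were lower in Tet1CD than in Tet2CD for 24 of 42 members (median log2 ratio -1.13), DNA methylation genes for 7 of 20 (-0.50) and pluripotency genes for 4 of 5 (-1.71). Matrix genes were higher for 12 of 35 (0.58), p53 genes for 6 of 26 with 1 lower (0.63), inflammatory genes for 3 of 14 (0.51), TGF-beta genes for 3 of 16 (0.38, and 0.25 with TPM), unfolded protein stress genes for 3 of 22 (0.36, and 0.22 with a minimum of 200 counts) and leukocyte markers for 5 of 5 (1.72). The BMP median was 0.93 (percentile 98.34), but 0.56 with a minimum of 10 counts, and list means gave percentile 85.35. Its member Bmper was 3.96-fold higher (2.3 to 7.12) and was 1 of 2 members that reached 50 counts in Tet1CD alone, without which the median turned to -0.30 over 3 genes. Imprinted genes went both ways, with a median of 0.46 (percentile 99.99, but 94.55 with list means), Osbpl5 2.37-fold (1.87 to 3.03) and Igf2 2.2-fold (1.9 to 2.54) higher and Peg10 3.1-fold (2.34 to 4.17) and Nnat 2.53-fold (1.97 to 3.27) lower. The endothelial gene Eng was 2.39-fold higher (1.95 to 2.94; list median 0.94), and the reprogramming factors had a median of -0.78 (percentile 0.79, but 5.85 with list means). In total 442 of 8318 genes were higher and 512 lower (11.5%). The share of higher calls was 46.3% with TMM factors, 37.2% with total counts and 34% with TPM, and the median of all genes moved from -0.008 to -0.101 and -0.138.

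**Figure D3:**
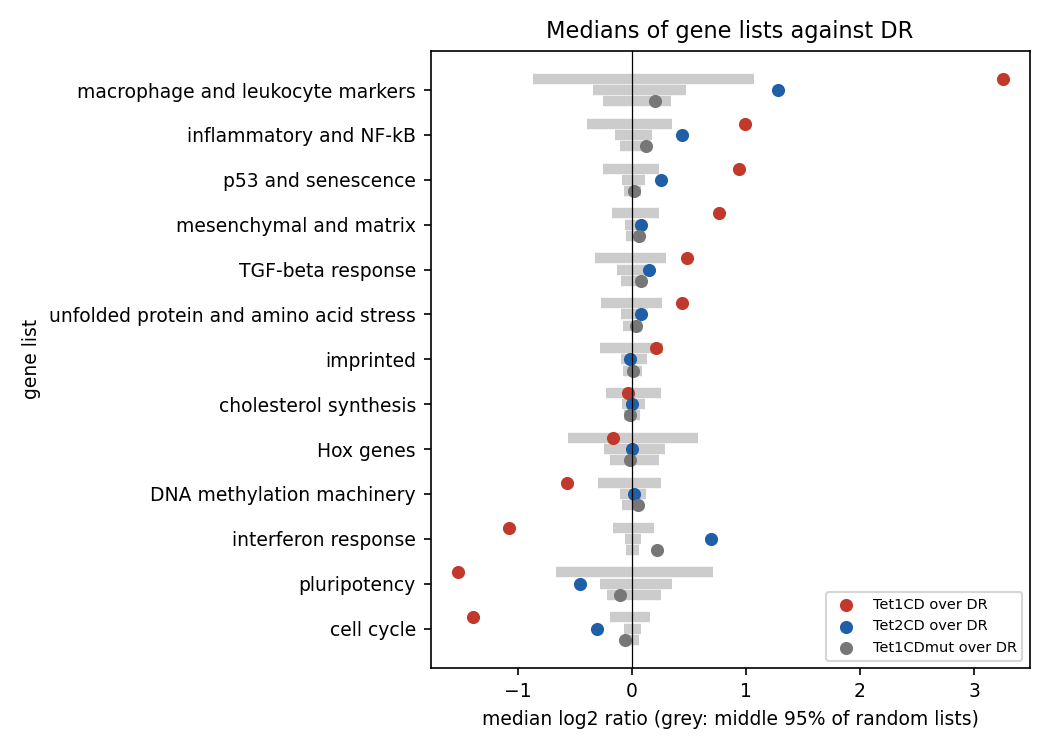
Median log2 ratio against DR of 13 gene lists in Tet1CD (red), Tet2CD (blue) and Tet1CDmut (grey points), with grey bands for the middle 95% of matched random lists. The interferon response median is -1.08 in Tet1CD and 0.69 in Tet2CD, with members behind these medians that are not all the same. The cell cycle median is -1.40 in Tet1CD and -0.31 in Tet2CD.

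Changes relative to the mutated form were set beside each other for both constructs, since these comparisons share no library. Among 8134 genes measured in both, 50 of the 85 genes higher in Tet2CD than in Tet2CDmut were also higher in Tet1CD than in Tet1CDmut, where independent lists would share 4.65. Of 15 genes lower in Tet2CD, 10 were lower in Tet1CD, where 1.12 would be shared. The 445 genes higher in Tet1CD had a median log2 ratio of 0.32 in the Tet2 comparison (percentile 100.0 of 2000 random lists), and the 605 lower genes had one of -0.17 (percentile 0). Across genes, which are not independent replicates, Pearson's r was 0.389 and Spearman's rho 0.293.

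The hMeDIP-seq peaks, regions in which the authors' peak caller found enrichment, were used to ask where hydroxymethylated DNA lay in each culture. The Tet1CD list held 55907 peaks over 86.6 Mb with a median width of 1355 bp, and the Tet2CD list 20050 peaks over 29.1 Mb with a median width of 1259 bp. The median peak score, which is the authors', was 78.8 and 64.8. Of the Tet2CD peaks 47.8% (47.1 to 48.5) overlapped a Tet1CD peak by at least 1 bp, against 6.47% after shuffling within chromosomes, and 17.2% of the Tet1CD peaks (16.8 to 17.5) overlapped a Tet2CD peak, against 2.34%. These shares depended on the lengths of the lists, since with as many top-scoring Tet1CD peaks as Tet2CD peaks they were 26.8% and 26.7%. With a score of at least 100 in both lists they were 51.8% and 6.86%. Overlap grew with the score, from 9.7% of the 13977 lowest-scoring to 30.3% of the 13977 highest-scoring Tet1CD peaks and from 37.0% to 64.0% between the 5013 lowest and 5013 highest of Tet2CD. On placed chromosomes the highest-scoring peaks were at mm9 chromosome 4, 118218839 to 118221806 (score 3100), in Tet1CD and chromosome 9, 35112438 to 35113923 (score 2985.04), in Tet2CD, and each overlapped a peak of the other list. The highest score of all Tet2CD peaks, 3098.63, was on unplaced sequence. No filter for repeated sequence was applied here, so high scores and their overlap need not reflect hydroxymethylation. Genes near the peaks were not analysed here for want of an mm9 annotation. The number of peaks also depends on sequencing depth and on the control, which are not given in the sources used here.

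Chromosome X held 3.09% of Tet1CD peaks (2.95 to 3.24; 1728 peaks) and 1.09% of Tet2CD peaks (0.957 to 1.25; 219 peaks), a ratio of 2.83. Over the 19 autosomes the ratio of the shares ranged from 0.846 to 1.08. Chromosome Y with its unplaced sequence held 0.551% of Tet1CD peaks (308) and 0.14% of Tet2CD peaks (28). Of the Tet1CD peaks on X 9.55% (165 of 1728) overlapped a Tet2CD peak, against 17.4% on autosomes. The share on X is limited by the low number of Tet2CD peaks there, 219, so it does not show less agreement between the lists on X.

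**Figure D4:**
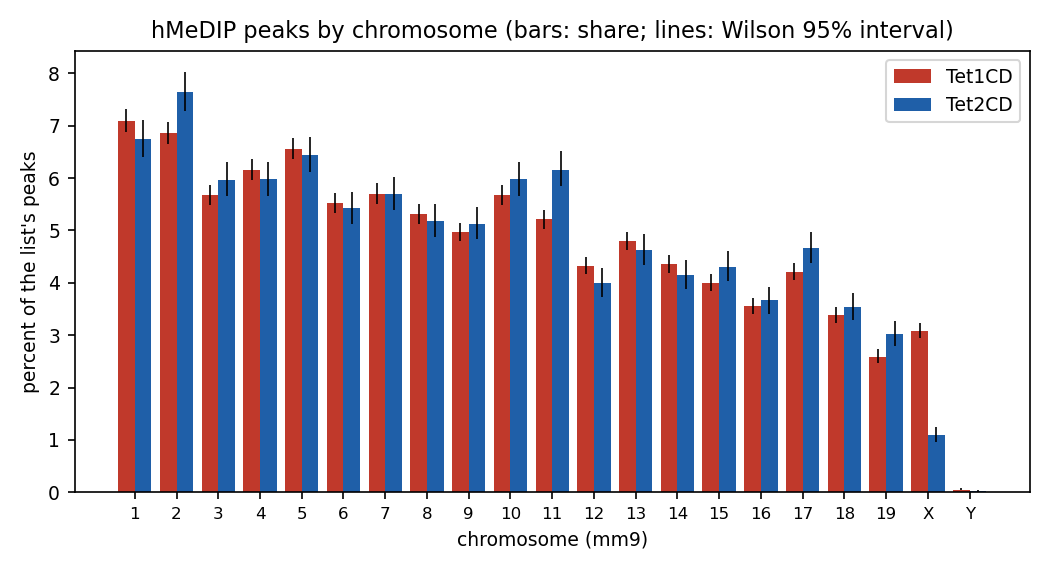
Percent of each list's hMeDIP peaks on each mm9 chromosome, in red for Tet1CD and blue for Tet2CD, with lines for the Wilson 95% interval. The X chromosome holds 3.09% of Tet1CD and 1.09% of Tet2CD peaks, while autosomes differ by factors of 0.846 to 1.08.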

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

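The values here come from the comparisons fixed in advance, and the differences between the constructs were not tested, since each group has 1 library. Genes are given because Tet1CD over Tet1CDmut and Tet2CD over Tet2CDmut passed the rule of size in opposite directions, and lists because both medians stood apart from random lists in opposite directions. The 7 genes lower in the Tet1 and higher in the Tet2 comparison are about as many as independent lists would share, 6.32, and 0 genes were higher in the Tet1 and lower in the Tet2 comparison, where 0.821 would be shared. The differences below are the log2 ratio of the Tet1 comparison minus that of the Tet2 comparison. Among interferon-inducible genes, Ifit1 had -1.49 and 1.20 (difference -2.69) and Ifit3 had -1.25 and 1.56 (difference -2.81). The median of the interferon response list was -1.25 and 0.38 (difference -1.63). The members behind these medians were not all the same. Of those that fell most in the Tet1 comparison, Iigp1, Gbp2 and Igtp were also lower in Tet2CD than in Tet2CDmut. Their counts were 554, 2612 and 1584 against 691, 4150 and 2046, while Psmb8 held 449 against 408. Of those that rose most in the Tet2 comparison, Oas3 and Dhx58 held 110 and 80 counts in Tet1CD. Tet1CDmut held 96 and 32 of them, while Ifit3 was lower in Tet1CD. The median of the TGF-beta response list was 0.31 and -0.15 (difference 0.46). The TGF-beta value of 0.31 became 0.14 with TPM and 0.19 with total counts, and the percentile of -0.15 moved from 1.27 to 4.25 with list means, so that the list no longer stood apart in the Tet2 comparison. Prkcb had -2.85 and 1.21 (difference -4.06), with 123 counts in Tet1CD, 1186 in Tet1CDmut, 858 in Tet2CD and 356 in Tet2CDmut. Its 957 counts in DR lie near the Tet2CD count, so the Tet2 ratio comes from a low value in Tet2CDmut. Spock2 had -3.09 and 1.33 (difference -4.42), Pipox -1.50 and 1.02 (difference -2.52), Pllp -1.45 and 1.06 (difference -2.50) and Unc93a -1.04 and 1.04 (difference -2.09).

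The deposited table of the whole series, used in no comparison, gave Tet1 a TPM of 346.81 in the column named DR, whereas the DR library's own file gives 12.88. The 346.81 belongs to Tet1CD in the single files. All 5 columns of that table matched, within 0.06 TPM, the single file of another library than the one they are named for: DR held Tet1CD, Tet1CD held Tet1CDmut, Tet1CDmut held Tet2CD, Tet2CD held Tet2CDmut and Tet2CDmut held DR. Of the 2 sets of names, those of the single files put the highest Tet1 counts under Tet1 constructs and the highest Tet2 counts under Tet2 constructs.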

How the results depend on the processing

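Removal of the length trend, the restriction to genes with whole expected counts and list medians without members that reached 50 counts in the first library of a comparison alone were chosen only after the data were seen, and the other alternatives were fixed in advance. Gene counts stayed within 1.5 times the reported ones in 90 cases, which include all counts with DESeq2 size factors, total counts, a prior count of 0.5, log2(TPM + 1) and the length trend removed. Leaving out a library was not possible with 1 per group. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers. Percent of genes with a peak within 5 kb of the start, with its alternatives of 1 kb and a score of at least 100, was not run for lack of an mm9 annotation. Depth limits genes under 50 counts, and peak counts move with a depth that is not given in the sources used here.

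Lower and higher count minimums admit more and fewer genes by construction. With a minimum of 10 counts, 1141 genes were higher and 1042 lower in Tet1CD than in DR, 218 and 125 in Tet2CD than in DR, 55 and 38 in Tet1CDmut than in DR, 107 and 94 in Tet2CDmut than in DR, 1090 and 1063 in Tet1CD than in Tet1CDmut, 221 and 113 in Tet2CD than in Tet2CDmut, 838 and 845 in Tet1CD than in Tet2CD, 917 and 843 in Tet1CD than in both references, and 102 and 37 in Tet2CD than in both. With a minimum of 200 counts, in the same order, 291 were higher and 219 lower, 34 and 3, 2 and 1, 15 and 3, 274 and 256, 26 and 3, 193 and 189, 254 and 190, and 15 and 1. With only genes whose expected counts were whole in all libraries, 3103 with 50 counts, they were 240 and 230, 23 and 15, 1 and 0, 7 and 4, 213 and 256, 23 and 4, 170 and 175, 191 and 188, and 12 and 1.

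Of 334 list medians, 329 kept their sign and lay within the 95% binomial interval of the reported median over the list's members, a wide limit for short lists, and 240 lay within 0.1 of the reported value. In 18 cases the median moved by over 1.5 times and over 0.1. With a minimum of 10 counts these were pluripotency (-0.05) and leukocyte markers (0.57) in Tet2CD over DR, the inflammatory list in Tet2CD over Tet2CDmut (0.27) and BMP in Tet1CD over Tet2CD (0.56). With a minimum of 200 counts they were DNA methylation (-0.89) and unfolded protein stress (0.27) in Tet1CD over DR, TGF-beta in Tet1CD over Tet1CDmut (0.63), unfolded protein stress in Tet1CD over Tet2CD (0.22), and the inflammatory list in Tet2CDmut over DR (0.10) and Tet2CD over Tet2CDmut (0.31). With log2(TPM + 1) they were TGF-beta (0.29, 0.14 and 0.25) and unfolded protein stress (0.25, 0.27 and 0.23) in Tet1CD over DR, Tet1CDmut and Tet2CD, and with total counts TGF-beta in Tet1CD over Tet1CDmut (0.19). Without the members that reached 50 counts in Tet1CD alone, the BMP median of Tet1CD over Tet2CD turned to -0.30 over the 3 genes left. The epithelial median of Tet2CD over DR turned to 0.19 with a minimum of 200 counts, which leaves fewer genes. The matrix median of Tet1CD over DR was 0.57 and the cell cycle median of Tet1CD over Tet1CDmut -1.54 with log2(TPM + 1), and the leukocyte median of Tet1CD over Tet1CDmut was 2.56 with a minimum of 10 counts, which admits more genes. Percentiles stayed on their side of the limits in 113 cases. Without matching on expression, percentiles became 3.1 for reprogramming factors in Tet1CD over Tet1CDmut, 2.65 for TET enzymes in Tet2CD over DR and 94.55 for glycolysis in Tet1CDmut over DR. With list means in place of medians they became 5.5 and 5.85 for reprogramming factors in Tet1CD over Tet1CDmut and over Tet2CD, 86.55 for TET enzymes in Tet1CD over DR, 40.0 and 96.45 for the epithelial list in Tet2CD and Tet1CDmut over DR, 4.25 for TGF-beta and 91.15 for the inflammatory list in Tet2CD over Tet2CDmut, 85.35 for BMP and 94.55 for imprinted genes in Tet1CD over Tet2CD, 95.1 for glycolysis in Tet1CDmut over DR, and 93.6 and 88.3 for neural genes in Tet1CD over DR and over Tet1CDmut. The cause was not tested for any change of scaling, matching or summary.

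With a score of at least 100, fewer peaks remained, 18051 in Tet1CD and 2389 in Tet2CD, of which 6.86% and 51.8% overlapped the other list. A reciprocal overlap gave 14.7% and 40.9%, and lists of equal length 26.7% and 26.8%.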

Other observations

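The tests of explanations given here were all chosen only after the results were seen, as were the genes named here that the rule for named genes leaves out. Germline genes below 50 counts had a higher summed count in Tet1CD, a large part of it from 5 genes. Over 55 listed genes the summed count was 366 in Tet1CD, 142 in DR, 146 in Tet1CDmut, 146 in Tet2CD and 128 in Tet2CDmut, a 2.83-fold excess over DR (95% counting interval 2.32 to 3.46). Random sets of 55 equally low genes, matched on the mean count of the 4 other libraries, had a median of 1.28-fold (middle 95% 0.82 to 2.01), and the germline sum lay at percentile 99.94 of 10000 such sets. Of these germline genes 11 had 10 or more counts in Tet1CD and 3 in DR. The 5 with 10 or more counts in Tet1CD and at most 3 in DR and both mutated forms were Tuba3b (42 counts), Taf7l (30), Asz1 (21), Sohlh2 (21) and Slc25a31 (18). They held 132 of the 366 counts, and the other 50 genes summed to 234 against 138 in DR, 1.86-fold (1.5 to 2.31). That lies within the middle 95% of the random sets, 0.82 to 2.01, which were drawn for all 55 genes. The percentile of 99.94 thus holds with the 5 genes, which were picked for their counts in Tet1CD, and was not computed without them. Dppa2 held 19 counts in Tet1CD and 0 in DR and Tet1CDmut. The 13 members of the Psg family in the files summed to 1438 counts in Tet1CD, 49 in DR, 48 in Tet1CDmut, 86 in Tet2CD and 33 in Tet2CDmut, and 2 of the 13, Psg23 and Psg29, reached 50 counts.

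A pair of gene models outside the rule for named genes stood out by size. Gm11127, which the gene table at hand also lists under the class I histocompatibility name H2-K1, held 11094 counts in Tet1CD, 117 in DR, 38 in Tet1CDmut, 430 in Tet2CD and 54 in Tet2CDmut. It was 104.1-fold higher in Tet1CD than in DR (86.8 to 126.0), 385.8-fold higher than in Tet1CDmut (280.9 to 545.5) and 7.66-fold higher in Tet2CD than in Tet2CDmut (5.76 to 10.4). Reads shared with related histocompatibility genes were not examined. A430078G23Rik held 2577 counts in Tet1CD, 59 in DR and 21 in Tet1CDmut, a 162.2-fold difference from Tet1CDmut (105.9 to 262.5).

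DR held more counts than the mutated forms of genes that were 16-fold or more higher in Tet1CD than in both of these. Over 11 such genes, chosen without the DR library, DR held 483 counts against 242.1 at the level of the mutated forms, an excess of 0.796% of the Tet1CD level (0.657 to 0.945). A candidate explanation is that reads of the Tet1CD library entered the DR library. With 1 common share fitted to these same genes, 10 of the 11 lay within its counting interval. A430078G23Rik, at 59 counts, lay above its predicted 39.9. Since the share was fitted to the genes on which it was checked, this count cannot decide for or against such reads. That share, added to the Tet1 level of the Tet2 libraries, would give 61.4 counts of Tet1 in DR, where 176 were found, which argues against Tet1CD reads as the only source of Tet1 there. Low expression of these genes in the DR culture and reads from Tet1CDmut, which has no other marker than Tet1, stay open and were not tested.

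The 5 leukocyte markers measured in Tet1CD rose together, with Itgam at 256 counts. Leukocytes in the culture would bring their abundant transcripts. Tyrobp, Fcer1g, C1qa, C1qb, C1qc and Ctss, picked after the values were seen, summed to 29 counts in Tet1CD and 5 in DR. Lyz2, a measured marker outside these 6, held 98 counts in Tet1CD and 25 in DR. Both Tet1CD values lay below that of Itgam, which argues against leukocytes as the source of the whole increase. The argument is limited to these chosen transcripts in 1 library. A smaller contribution cannot be told apart from other causes, since the 15 markers under 50 counts summed to 4.73-fold the DR level while Ptprc, which leukocytes share, held 3 counts against 6, too few to decide. The lowest median of the list over 3 other scalings was 3.1. These scalings moved the median log2 ratio of all genes from -0.005 to no lower than -0.189, so this outcome was fixed in advance. It shows only that differences between these scalings are too small to give the list's median of 3.25. Of the 20 markers 5 had 10 or more counts in DR, the same 5 that were measured, and 0 stand in another list, and an increase within the fibroblasts themselves stays open and was not tested.

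The share of hMeDIP peaks on X was larger in Tet1CD than in Tet2CD. A longer list with weaker peaks could raise it, but among as many top-scoring Tet1CD peaks as Tet2CD has the share on X was 4.58%, farther from the 1.09% of Tet2CD. More XX cells in the Tet1CD culture could raise it as well and would lower the share on Y. Chromosome Y with its unplaced sequence held 0.551% in Tet1CD and 0.14% in Tet2CD, but 279 of 308 and 24 of 28 of these peaks lay on the unplaced sequence. On placed Y the shares were 0.0519% (0.0361 to 0.0745) and 0.02% (0.00776 to 0.0513), with overlapping intervals. The shares on Y therefore cannot decide on XX cells. Differences in sequencing depth or in the control, and a difference between the Tet1CD and Tet2CD constructs, stay open and were not tested.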
